A study of Homo sapiens with 6 samples.

How the data were processed

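Libraries of T47D cells were sequenced on an Illumina NovaSeq instrument after TRIzol extraction of RNA and NEBNext Ultra library preparation, per the labels' protocols. The protocol text, given alike for control and exposed samples, places extraction 48 h into exposure. The deposited table holds whole-number read counts per gene for the 6 libraries, made by the authors against GRCh38 per the submitters' processing notes. The aligner, counting tool, annotation release, strand setting and any poly(A) selection are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be told apart. All 58735 gene IDs of the table were found in GENCODE 29 with the same coordinates, strand and gene type, so coordinates are those of GRCh38. Gene symbols are those of the table.

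Groups and replicate numbers came from the sample titles, 3 control and 3 exposed libraries. The design text calls the replicates biological but does not say that they came from separate cultures. The p-values set the group difference against the spread between these samples, and need not hold for other cultures. Pairs of libraries within a group had a chi-square of 7.11 to 14.9 per degree of freedom over genes, and no pair held identical values. Of 58735 genes, 26945 had no count in any library. Total counts ran from 30970218 to 36878525.

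Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr at its defaults (minimum count 10, minimum total 15) kept 17337 genes, TMM factors (0.948 to 1.04) scaled the libraries, and the robust quasi-likelihood fit compared exposed with control. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. CPM values use the TMM-scaled library sizes, and errors are the SD over 3 libraries. The biological coefficient of variation was 9.61%. In counts simulated from these libraries over 17337 genes, the test recovered 67.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold, and called 20 of 17109 unchanged genes (0.117%). Thus 17109 of 17337 simulated genes were unchanged, whereas 43.9% of tested genes passed in the data. The genes counted as recovered all had a minimum mean count, so these rates need not hold for this comparison.

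Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 30 lists of at least 5 tested genes, and again with an estimated correlation and with fry. The lists were the AhR battery, NRF2 antioxidant, metallothionein and zinc export, heat shock, ATF4 integrated stress, ER chaperone, NF-kB inflammatory, interferon-stimulated, estrogen receptor target, luminal identity, basal epithelial, mesenchymal and matrix, YAP and TGF-beta target, Wnt target, mitosis, DNA replication, p53 target, cholesterol, fatty acid synthesis, fatty acid oxidation and storage, hypoxia and glycolysis, lysosome and autophagy, iron handling, nuclear oxidative phosphorylation, mitochondrial genome, ribosomal protein, histone, immediate early, steroid receptor target and non-epithelial marker lists. Of 584 list entries, 1 matched no gene in the table. Some genes are in several lists, as HMOX1 and FTL are in the NRF2 and iron handling lists, so the lists are not independent. In the simulated counts camera called the 1 shifted list and no other. Those counts were drawn gene by gene without correlation, so they cannot show how often camera calls an unshifted list of correlated genes.

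The test, the lists, the naming rule and all alternatives but the last below were fixed before the data were examined. The rule names, among genes past the threshold with non-overlapping groups and a mean of at least 1 CPM, the 8 largest log2 rises and falls and the 4 largest rises and falls in CPM. It adds 13 genes whatever their result (CYP1A1, CYP1B1, AHRR, TIPARP, HMOX1, NQO1, ESR1, PGR, GATA3, ERBB2, MKI67, CDH1 and VIM) and up to 4 members of each list with the smallest adjusted p. Genes named as exceptions to a list's direction, and CYP1A2 and MT-CO1, MT-ND4L in figure captions, were chosen after their values were seen. Some genes that the rule takes are not reported here.

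The alternatives were size factors of the DESeq2 type, no or a stricter low-count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, a fold minimum, a test against a 1.5-fold change, protein-coding genes alone and removal of mitochondrial genes. A per-library correction for GC content and gene length was added after seeing the data. Leaving out a library leaves 2 in its group.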

Results

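RNA was sequenced from T47D cells, an established human breast cancer line of the luminal type that expresses the estrogen and progesterone receptors. The series concerns fine airborne particulate matter (PM2.5) and a breast cancer subtype, and compares 3 control libraries with 3 libraries of exposed cells, described as biological replicates. The sample titles code the control libraries CK and the others CQ, and the design text calls the second group only an experimental treatment. That this treatment was PM2.5 is inferred from the series title and from an extraction protocol worded alike for control samples, and "exposed" is used in that sense throughout. The dose is not given in the sources used here. Deposited counts per library summed to 36024874, 34696540 and 35165644 in control replicates 1 to 3, and to 35850261, 30970218 and 36878525 in exposed replicates 1 to 3. Between 24597 and 25059 genes had at least 1 count in a control library, and between 23949 and 24402 in an exposed library. Transcripts of the mitochondrial genome took 8.98% to 9.65% of the counts in controls and 8.97% to 9.71% in exposed libraries.

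The comparison asks how the RNA of these cells differed after exposure. The largest rise was that of CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), from 1.58 ± 0.329 to 2122 ± 95.9 CPM (counts scaled to library size; mean ± SD, n = 3 per group), or 1342-fold. HMOX1, which degrades heme, rose 8.51-fold, and the stress-response genes GDF15 and DDIT3 rose 31.1-fold and 13.7-fold. The estrogen receptor gene ESR1 fell from 167 ± 12.2 to 67.1 ± 3.45 CPM and the progesterone receptor gene PGR from 821 ± 90.8 to 299 ± 17.1 CPM (n = 3 per group). Genes of cholesterol synthesis and of lysosomes rose together, while genes of DNA replication and interferon-stimulated genes fell.

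Of 17337 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7610 (43.9%) changed, 3778 higher and 3832 lower in exposed cells. Most changes were small: 4117 of these genes changed by less than 1.5-fold, and 634 rose and 964 fell by at least 1 on the log2 scale. The values of 9002 tested genes (51.9%) did not overlap between the groups, against 10% by chance for 3 against 3. Of 13556 protein-coding genes tested, 3421 rose and 3150 fell. The first principal component of log2 CPM held 62.0% of the variance and separated the groups, with Pearson's r across genes of 0.988 to 0.990 between libraries of a group and 0.967 to 0.972 between groups.

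The fixed naming rule took the 8 largest log2 rises and falls among genes with a mean of at least 1 CPM. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610, minus strand) led the rises with a log2 fold change of 10.39 ± 0.13 (SE), adjusted p = 7.6e-33 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Next came GCNT3, a mucin-type glycosyltransferase, at 5.09 ± 0.36, GDF15, a stress-induced cytokine (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand), at 4.96 ± 0.13, and the metallothionein MT1M at 4.49 ± 0.12. DDIT3, which encodes the stress factor CHOP, GPX2, a glutathione peroxidase, AKR1C2, an aldo-keto reductase, and DUSP13, a phosphatase, had log2 fold changes of 3.78, 3.70, 3.67 and 3.59. MT1M and AKR1C2 belong to families of near-identical genes, so reads may have been split between members.

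Among the falls taken by the same rule was that of PLCL1 (ENSG00000115896, chromosome 2, 197804702 to 198572581, plus strand) at -4.29 ± 0.48 (log2 fold change ± SE). PLCL1 had 0 counts in exposed replicate 3. LRRN3, EGR3, ABCC12, ADRA2A, AC055854.1 and PDZK1 were also among them, with log2 fold changes of -3.97, -3.89, -3.56, -3.53, -3.52 and -3.36. EGR3 is an early growth response factor, ADRA2A an adrenergic receptor and PDZK1 a scaffold protein. AC055854.1 overlaps EGR3 on the opposite strand, and with the strand setting not given their reads cannot be told apart. EGR3 fell from 5.09 ± 0.778 to 0.349 ± 0.235 CPM (n = 3 per group).

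Counted in CPM rather than in folds, abundant transcripts led. The light chain of an amino acid transporter, SLC7A5, rose from 3017 ± 213 to 6852 ± 328 CPM, and the mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 from 5239 ± 166 to 11531 ± 874 and from 2505 ± 107 to 6376 ± 398 CPM (n = 3 per group). The epithelial keratins KRT8 and KRT19 fell from 8154 ± 553 to 3301 ± 400.1 and from 7504 ± 468 to 3473 ± 708 CPM. KRT8 has many processed pseudogenes with which its reads could be shared.

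**Figure D1:**
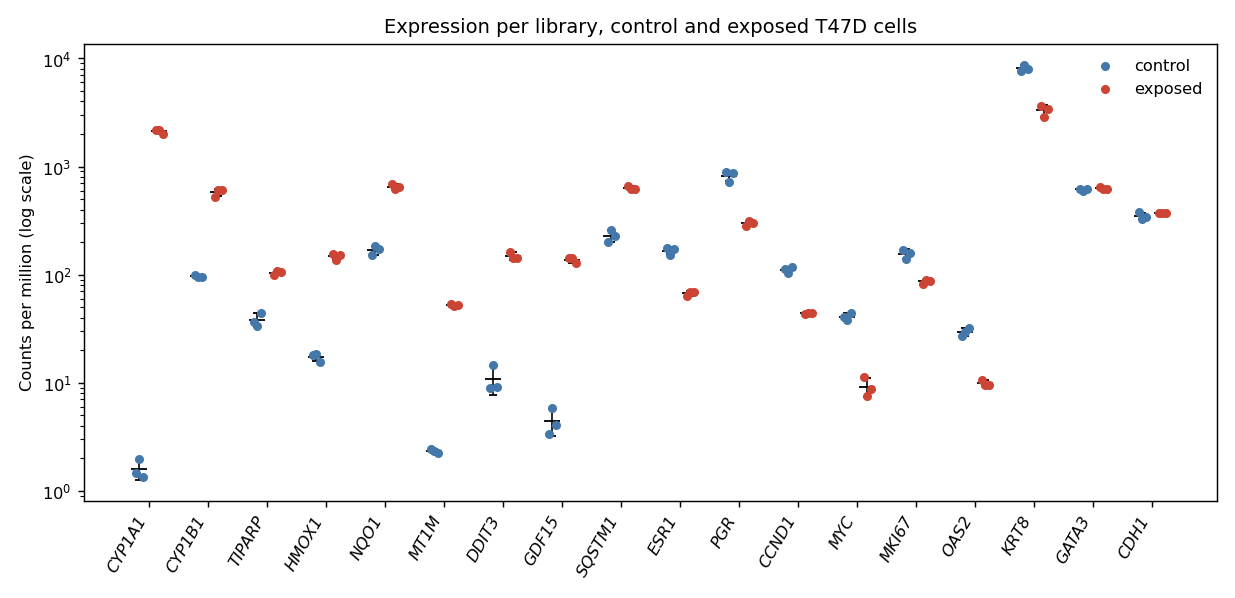
CPM (scaled counts) on a log axis for 18 genes in each of the 3 control (blue) and 3 exposed (red) T47D libraries; dots are libraries, horizontal marks group means and bars the SD. CYP1A1 went from 1.58 ± 0.329 to 2122 ± 95.9 CPM, ESR1 and PGR lay lower in every exposed library than in every control library, and GATA3 and CDH1 did not pass the test.

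The AhR battery, genes induced through the receptor for polycyclic aromatic ligands, had 9 of 12 tested members higher and 3 that did not pass (camera adjusted p = 2.8e-33). CYP1B1, another cytochrome P450, rose 5.99-fold from 96.3 ± 2.13 to 577 ± 47.3 CPM (n = 3 per group), and the feedback regulators AHRR and TIPARP rose by log2 values of 1.64 ± 0.17 and 1.44 ± 0.09 (SE). The list of NRF2 antioxidant genes had 21 of 22 members higher (camera adjusted p = 2.9e-50), among them HMOX1 at 3.09 ± 0.09, GCLM, a subunit of the enzyme that makes the glutathione precursor, at 2.45 ± 0.10, and NQO1, a quinone reductase counted in both lists, at 1.94 ± 0.08 (log2 ± SE). All 5 tested genes of the metallothionein and zinc export list rose (camera adjusted p = 1.1e-43), including MT1X at 3.16, MT1F at 2.67 and the zinc exporter SLC30A1 at 2.06. Adjusted over the list alone, 9, 22 and 5 members of these 3 lists rose.

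Of 20 genes of the ATF4 integrated stress list, 16 rose and 2 fell (camera adjusted p = 1.4e-20). ATF4 itself rose by 1.17 ± 0.08 (log2, SE), the cystine transporter subunit SLC7A11 by 2.19 ± 0.10 and NUPR1 by 1.79 ± 0.09, whereas ATF5 and STC2 fell. Chaperones of the endoplasmic reticulum (ER) followed, with 12 of 16 members of the ER chaperone list higher and 2 lower (camera adjusted p = 3.2e-07). HSPA5, the main chaperone of the ER, rose from 665 ± 37.6 to 1673 ± 33.8 CPM (n = 3 per group) and HERPUD1 by 1.75 ± 0.08 on the log2 scale. The members that fell were XBP1, a transcription factor of the unfolded protein response, and EDEM1. Cytosolic heat shock genes moved both ways, 4 of 15 higher and 6 lower (camera adjusted p = 0.63), with HSPB8 at 1.09 and HSPA1B at 0.77 but DNAJA1 at -0.98 and HSPH1 at -0.87. HSPA1B shares most of its sequence with HSPA1A. Adjusted over the list alone, the numbers that rose and fell were 16 and 2, 12 and 2, and 4 and 6.

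Estrogen receptor targets were lower: 21 of 24 tested members fell and 1 rose (camera adjusted p = 1.3e-23; 23 fell and 1 rose adjusted over the list alone). PGR (ENSG00000082175, chromosome 11, 101029624 to 101130524, minus strand) had a log2 fold change of -1.46 ± 0.08 (SE), the chemokine CXCL12 -2.54 ± 0.09, the potassium channel KCNK5 -2.51 ± 0.14 and the cyclin CCND1 -1.34 ± 0.08. The member that rose was the small heat shock protein HSPB8. Of 20 luminal identity genes, 13 fell and 1 rose (camera adjusted p = 5.4e-08; the same counts adjusted over the list alone). ESR1 (ENSG00000091831, chromosome 6, 151656691 to 152129619, plus strand) was at -1.31 ± 0.08, the secreted protein AGR2 at -1.54 ± 0.08 and the prolactin receptor PRLR at -1.16 ± 0.09. The luminal factor GATA3 was at 0.04 ± 0.08, the receptor tyrosine kinase ERBB2 at -0.09 ± 0.07 and the adhesion protein CDH1 at 0.08 ± 0.08, and none of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.72, 0.31 and 0.42).

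Markers of other cell states were also counted. Of 10 basal epithelial genes 5 rose and 1 fell (camera adjusted p = 0.17), with LAMB3, a chain of an epithelial laminin, at 0.58 and the cadherin CDH3 at 0.35. Among 13 mesenchymal and matrix genes 2 rose and 4 fell (camera adjusted p = 0.75), ITGA5 at 0.68 and S100A4 at -0.70, and VIM, which encodes vimentin, stood at -0.29 ± 0.33 (SE) without passing. Of 19 non-epithelial cell markers 6 could be tested and 1 rose (camera adjusted p = 0.75). The most abundant, the collagen gene COL1A1, was at 61.6 ± 4.05 and 69.8 ± 1.43 CPM (n = 3 per group) and did not pass. The marker that rose, COL1A2, was at 0.598 ± 0.0448 and 1.17 ± 0.151 CPM (n = 3 per group), and its call ended without any library other than exposed replicate 3 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p from 0.060 to 0.087). Adjusted over the list alone, 5 basal genes rose and 1 fell, 2 mesenchymal genes rose and 4 fell, and COL1A2 no longer passed.

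Genes of DNA replication fell in 24 of 28 cases and rose in 3 (camera adjusted p = 1.6e-10). POLA1, the catalytic subunit of polymerase alpha, was at -1.32 ± 0.11, and the replicative helicase subunits MCM6 and MCM3 were at -1.27 ± 0.10 and -0.87 ± 0.07 (log2 ± SE). Of 24 mitosis genes 17 fell and 1 rose (camera adjusted p = 8.0e-06; adjusted p = 0.15 with an estimated correlation). The proliferation marker MKI67 fell from 156 ± 16.2 to 86.5 ± 3.52 CPM (n = 3 per group), with KIF20A at -0.94 and CCNB1 at -0.59 on the log2 scale. Replication-dependent histone genes moved both ways, 3 of 10 higher and 3 lower (camera adjusted p = 0.94), among them HIST1H4H at -0.68. The linker histone gene H1F0, at 0.58, is in that list although its expression does not depend on replication. Of 21 p53 targets 8 rose and 6 fell (camera adjusted p = 0.20), with GADD45A at 2.08 and BBC3 at 1.47. Adjusted over the list alone, the members that rose and fell numbered 3 and 24 for replication, 1 and 18 for mitosis, 3 and 3 for histones, and 8 and 7 for p53 targets.

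Interferon-stimulated genes fell in 17 of 20 cases (camera adjusted p = 1.2e-08; the same count adjusted over the list alone). OAS2 and OAS1, which sense double-stranded RNA, were at -1.58 ± 0.11 and -1.48 ± 0.12, and the ubiquitin-like ISG15 at -1.43 ± 0.12 (log2 ± SE). Of 14 NF-kB inflammatory genes 3 rose and 4 fell (camera adjusted p = 0.42; the same counts adjusted over the list alone), with the adhesion molecule ICAM1 at 1.72 and the apoptosis inhibitor BIRC3 at -0.84. Immediate early genes rose in 9 of 15 cases and fell in 3 (camera adjusted p = 0.099; the same counts adjusted over the list alone): ATF3 was at 1.56 and ZFP36 at 1.19, but MYC at -2.15 ± 0.12, or 40.7 ± 3.06 against 9.18 ± 1.83 CPM (n = 3 per group).

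YAP and TGF-beta targets fell in 10 of 17 cases and rose in 1 (camera adjusted p = 1.4e-04; the same counts adjusted over the list alone). PMEPA1 was at -1.67 ± 0.10 and ID1 at -1.91 ± 0.13 on the log2 scale (SE), and TGFB2, which encodes a TGF-beta ligand, had 56, 44 and 40 counts in control replicates 1 to 3 and 0, 1 and 0 in exposed replicates 1 to 3. The member that rose was LATS2, at 0.48, and CYR61, at -0.02, and AMOTL2, at 0.09, were among those that did not pass. The list joins both pathways and was tested as a whole, so its call cannot be assigned to either. Of 12 Wnt targets 5 fell and 2 rose (camera adjusted p = 0.044; adjusted p = 0.30 with an estimated correlation; the same counts adjusted over the list alone), with DKK1 at -2.30 and RNF43 at 1.57. The camera call of the Wnt list ended without control replicate 1 (adjusted p = 0.051), control replicate 2 (0.058), exposed replicate 2 (0.052) or exposed replicate 3 (0.064). Targets of the glucocorticoid, progesterone and androgen receptors rose in 6 of 12 cases and fell in 2 (camera adjusted p = 0.013; adjusted p = 0.20 with an estimated correlation). TSC22D3 and PER1 were at 1.35 and 1.28, and FKBP5 at -0.55. Adjusted over the list alone, 6 of these targets rose and 3 fell.

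Cholesterol synthesis and uptake genes rose in 20 of 23 cases and fell in 1 (camera adjusted p = 4.8e-16; 21 rose and 1 fell adjusted over the list alone). INSIG1, a sterol-regulated protein of the ER, went from 83.8 ± 1.87 to 221 ± 14.9 CPM (n = 3 per group), and MSMO1, an enzyme of sterol synthesis, was at 1.26 ± 0.09 (log2 ± SE). Of 14 fatty acid synthesis genes 4 rose and 3 fell (camera adjusted p = 0.94), with THRSP at -2.62 and MID1IP1, its paralog, at 1.43. Of 17 fatty acid oxidation and storage genes 3 rose and 4 fell (camera adjusted p = 0.098), among them PLIN4, a lipid droplet protein, at -1.95 and the coactivator PPARGC1A at 1.91. Both fatty acid lists gave the same counts adjusted over the list alone.

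Lysosome and autophagy genes rose in 24 of 28 cases (camera adjusted p = 1.4e-15; 24 rose and 1 fell adjusted over the list alone). The sialidase NEU1 was at 1.47 ± 0.08, the autophagy receptor SQSTM1 at 1.47 ± 0.08 and MAP1LC3B at 1.15 ± 0.07 (log2 ± SE). Among 12 iron handling genes 5 rose and 3 fell (camera adjusted p = 0.054; the same counts adjusted over the list alone). The ferritin light chain FTL, which has several processed pseudogenes, rose 3.47-fold, while the transferrin receptor TFRC fell from 1162 ± 116 to 369 ± 36.7 CPM and the iron exporter SLC40A1 from 386 ± 42.6 to 132 ± 7.68 CPM (n = 3 per group). Hypoxia and glycolysis genes fell in 8 of 24 cases and rose in 1 (camera adjusted p = 0.06; the same counts adjusted over the list alone), with the glycolytic enzymes ENO1 and PGK1 at -0.67 and -0.78. Without exposed replicate 3 that list was called lower (camera adjusted p = 1.5e-04, range over the camera settings 1.5e-04 to 0.77).

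**Figure D2:**
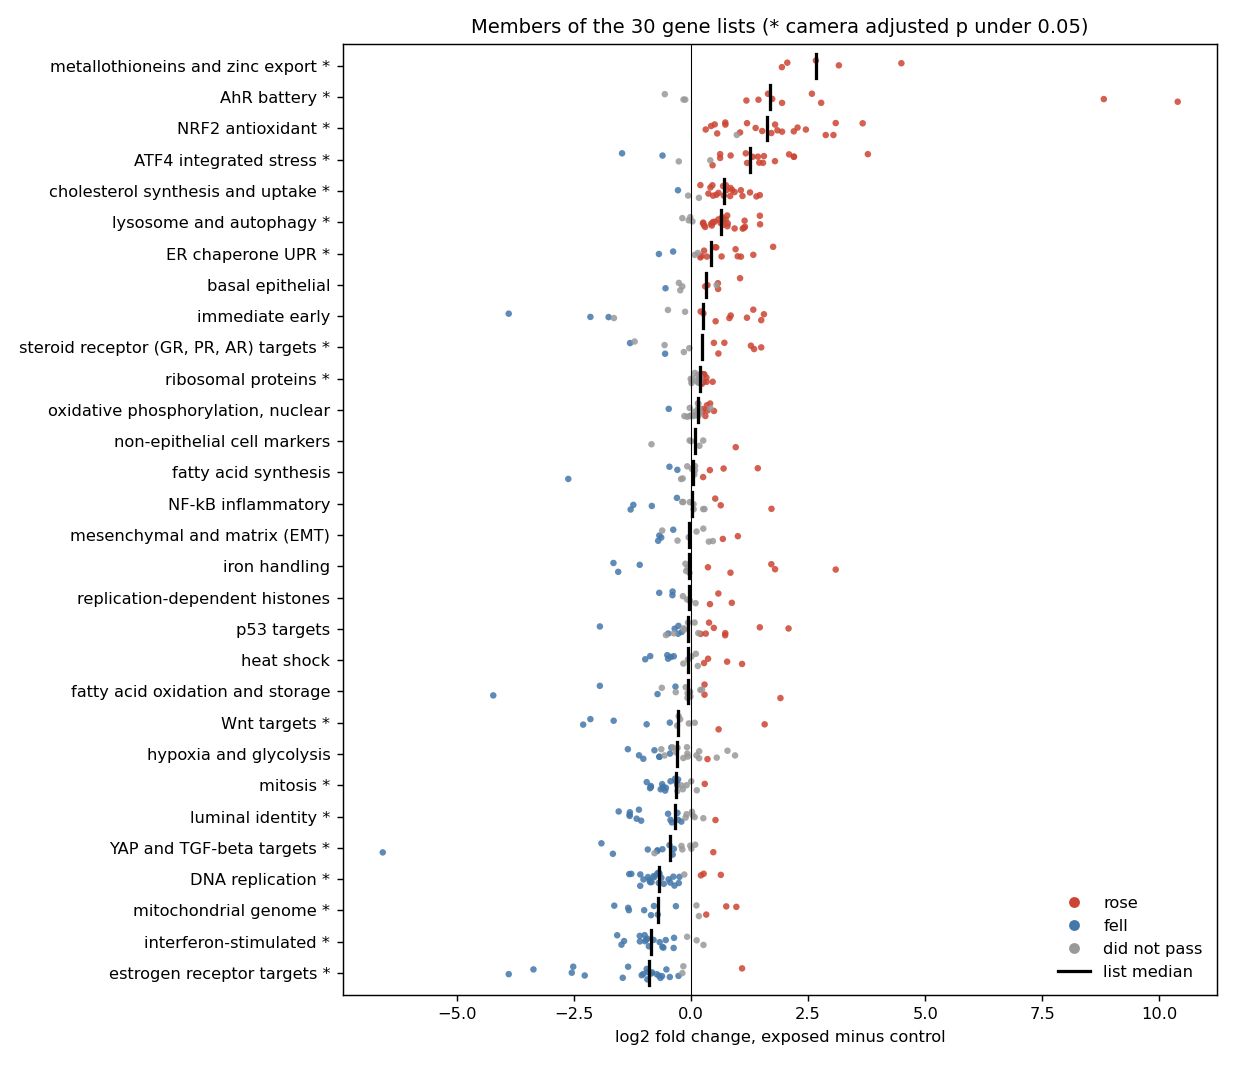
Log2 fold changes (exposed minus control, 3 libraries per group) of the tested members of the 30 gene lists, a dot per gene and a black bar at each list's median, with an asterisk where camera's adjusted p passed 0.05. All 5 metallothionein and zinc export genes lie to the right of 0 and 21 of 24 estrogen receptor targets fell; the fitted positions of CYP1A2, with no control count, and TGFB2, with 1 exposed count, depend on the prior count.

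Transcripts of the mitochondrial genome moved apart. Of 13 mitochondrial protein-coding genes 3 rose and 8 fell (camera adjusted p = 1.4e-04; adjusted p = 0.30 with an estimated correlation; the same counts adjusted over the list alone). MT-CO3, a subunit of cytochrome oxidase, fell from 4674 ± 164 to 1502 ± 119 CPM and MT-ND3, of complex I, from 1988 ± 151 to 793 ± 61.3 CPM. MT-ND6, encoded on the minus strand, rose from 1633 ± 191 to 3195 ± 363 CPM (n = 3 per group). With the strand setting not given, its reads cannot be told apart from those of plus-strand RNA over the same position. MT-ND5, on the plus strand, ends at the base before MT-ND6 and rose by 0.75 on the log2 scale. MT-CYB was at -0.71 ± 0.09 and MT-ND4 at 0.33 ± 0.10 on the log2 scale (SE). The call of MT-ND4 ended without control replicate 3 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, log2 fold change 0.26, adjusted p = 0.088, range over all settings 3.2e-04 to 0.088). Some of these genes overlap each other, and nuclear copies share their sequence. Nuclear genes of oxidative phosphorylation had 7 of 26 members higher and 1 lower (camera adjusted p = 0.11; the same counts adjusted over the list alone), with CYC1 at 0.49 and ATP5MC1 at -0.47.

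**Figure D3:**
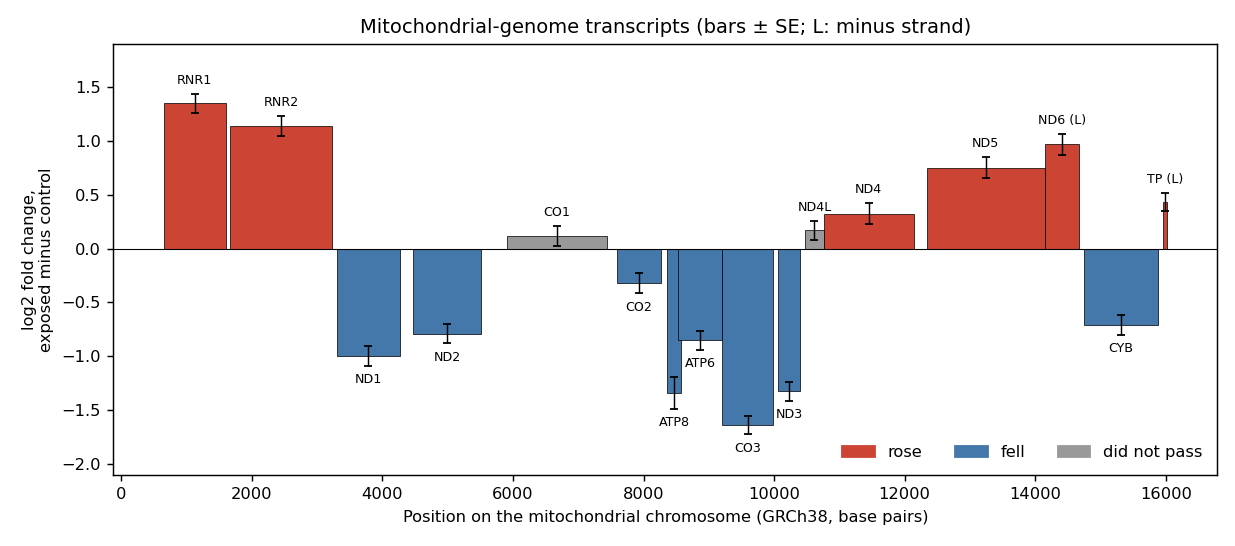
Log2 fold change (exposed minus control, 3 libraries per group; bars ± SE) of 16 tested genes along the mitochondrial chromosome, in base pairs of GRCh38, with the width of each bar giving the gene's extent. MT-RNR1 and MT-RNR2 rose by 1.35 and 1.14, MT-CO3 was at -1.64, and MT-CO1 and MT-ND4L (grey) did not pass the test.

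Ribosomal protein genes shifted by small amounts, 11 of 26 higher (camera adjusted p = 0.02; adjusted p = 0.74 with an estimated correlation; the same count adjusted over the list alone). RPL10A was at 0.46 ± 0.08 and RPS18 at 0.33 ± 0.09 on the log2 scale (SE). The camera call of the list ended without control replicate 1 (adjusted p = 0.077) or exposed replicate 1 (adjusted p = 0.067).

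Of the 30 lists, camera called 17, 9 higher and 8 lower. With an estimated correlation 12 calls held: the AhR, NRF2, metallothionein, ATF4, ER chaperone, cholesterol and lysosome lists higher, and the interferon, estrogen receptor target, luminal, YAP and TGF-beta, and DNA replication lists lower. The median, mean and camera test differed in sign for 6 lists, none of them called by camera with all 6 libraries: NF-kB, p53, fatty acid synthesis, iron handling, histones and immediate early genes.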

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

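The GC and length correction was chosen after the results were seen, and the other settings before. Demanding a log2 fold change of at least 1 left 1598 changed genes, and testing against a 1.5-fold change left 1498, by their own construction, against 7610. Other settings gave counts within 1.5 times that number: 7606 with DESeq2-type size factors, 7391 without a low-count filter, 7242 with a stricter filter, 7349 with DESeq2, 7614 with limma-voom, 6704 among protein-coding genes alone, 7592 without mitochondrial genes and 8466 with the GC and length correction. Leaving out a library gave 6262 to 7637. Over the settings applied to all genes, 46.9% to 51.9% of changed genes were higher, and no gene called as reported and again under another setting changed direction. All these settings scaled the libraries to each other, so directions are relative to the bulk of genes. The near-even shares therefore follow in part from the scaling, and a rise or fall of total RNA per cell would not be seen. Of all 7610 calls, 6099 were shared without control replicate 3, the fewest over these settings. Most named genes were picked for large changes or small adjusted p, so their calls were likely to hold. Of 140 named genes, 133 were called, 130 of them under every such setting. The exceptions were COL1A2 (adjusted p = 0.052 with the replicate block, range 0.023 to 0.087), MT-ND4 and RPL8, whose call ended without control replicate 3 (RPL8 adjusted p = 0.055, range 1.1e-04 to 0.055). COL1A1, not called, passed with DESeq2, with the GC and length correction and without control replicate 2. GATA3, not called, went from 0.04 to -0.045 with the GC and length correction (adjusted p = 0.53, range over settings 0.53 to 0.92); the cause was not tested. With control and exposed libraries of the same number as a replicate block, 6779 genes changed, 6749 of them among the 7610. Deviations of same-numbered libraries from their group means correlated across genes at -0.17, -0.15 and 0.01, the highest value for unlike numbers was 0.26, and not every library correlated best with its own number, so the numbers gave no pairing. The block changed the call of 1 list, hypoxia and glycolysis (adjusted p = 0.0066). That list was also called lower without control replicate 3 (0.029), exposed replicate 1 (0.043) or exposed replicate 3 (1.5e-04). Iron handling was called higher without exposed replicate 1 (0.023), 2 (0.027) or 3 (0.033), immediate early genes without exposed replicate 2 (0.022) and nuclear oxidative phosphorylation without control replicate 2 (0.029). Over the camera settings, camera's adjusted p ranged from 0.023 to 0.22 for iron handling, 0.022 to 0.34 for immediate early genes, 0.029 to 0.74 for nuclear oxidative phosphorylation, 0.020 to 0.30 for Wnt targets and 8.4e-04 to 0.74 for ribosomal proteins. Fry, which tests whether a list moves on balance and not against other genes, called 21 lists. It added the basal epithelial, p53, fatty acid oxidation and storage, iron handling and immediate early lists. Ribosomal proteins lost their call (fry adjusted p = 0.11). Of the 17 camera calls, 15 held under every left-out library. With 3 libraries per group small changes may be missed, as recovery at 1.5-fold was 67.2% in a simulation with far fewer changed genes. The numbers 7610 and 8466 are counts at this depth.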

Other observations

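The tests of further gene lists, of the mitochondrial transcripts, of ribosome biogenesis beside MYC and of clock phase were chosen after the results were seen. Genes of the circadian clock rose in 11 of 16 cases and fell in 1 (camera adjusted p = 6.5e-10; adjusted p = 0.073 with an estimated correlation). The clock repressor NR1D1 was at 2.22 ± 0.19 and the clock output factor DBP at 2.16 ± 0.10 (log2 ± SE), with CIART at 1.65 and PER3 at 1.20, while the activator ARNTL was at -0.82. Cytosolic tRNA synthetase genes, which charge tRNAs with amino acids, rose in 11 of 18 cases and fell in 2 (camera adjusted p = 3.2e-06; adjusted p = 0.17 with an estimated correlation), led by AARS at 1.38 and SARS at 1.21. Amino acid transporter genes rose in 9 of 15 cases and fell in 2 (camera adjusted p = 1.2e-04; adjusted p = 0.27 with an estimated correlation). Transcription factors of the bZIP family, as the table assigns them, rose in 24 of 42 cases and fell in 6 (camera adjusted p = 1.5e-07; adjusted p = 0.073 with an estimated correlation), with the small MAF genes MAFF and MAFG higher, MAFG at 1.75, and the NRF2 gene NFE2L2 at 0.75.

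Keratin genes fell in 6 of 11 cases (camera adjusted p = 4.5e-06; adjusted p = 0.27 with an estimated correlation), with KRT23 at -2.31 ± 0.12 and KRT15 at -1.57. Within the insulin-like growth factor axis, 3 of 12 genes rose and 5 fell (camera adjusted p = 0.12): IGFBP5, a binding protein, was at -2.89 ± 0.10 and the insulin receptor substrate IRS2 at 2.34 ± 0.13. Proteasome subunit genes rose in 10 of 31 cases and fell in 1 (camera adjusted p = 0.19), and class I antigen presentation genes rose in 7 of 15 and fell in 2 (camera adjusted p = 0.31), with NLRC5 at 1.41. Of 28 lists and transcription factor families added in this way, camera called 8, and each of the 8 calls was lost with an estimated correlation (adjusted p from 0.073 to 0.34). Some added lists hold genes already reported above, as DDIT3 is in the bZIP family and SLC7A11 among the amino acid transporters. Their calls are thus not independent of the earlier ones.

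The breadth of the change was weighed against technical causes. With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split of 10 with as many as 7610 genes, and the highest of the others gave 0 in edgeR's quasi-likelihood test, with at most 491 genes at an unadjusted p under 0.05. Each other split mixes the groups, so a group difference of any cause adds to its spread and leaves few calls. The splits therefore cannot separate exposure from another difference between the groups. A bias of GC content or gene length as the whole cause would have removed most calls, and after correction 8466 genes changed. The exposure may account for the breadth, and a difference in culture handling or library preparation between the groups, for which the labels give no record, was not tested.

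For the mitochondrial transcripts, 3 technical explanations were tested. Loss of short transcripts would lower short nuclear genes as well, but short minus long nuclear protein-coding genes differed by a median of -0.046 on the log2 scale (95% bootstrap interval -0.16 to 0.04), against a gap of 1.68 between the mitochondrial mRNAs that rose and fell. More RNA without a poly(A) tail in exposed libraries would raise nuclear genes of that kind with the mitochondrial rRNAs. Those genes had a median of -0.13 (-0.39 to 0.23) over 12 genes of at least 1 CPM, a minimum set after the value without it, -0.07 over 43 genes, was seen, against 1.24 for the rRNAs. Replication-dependent histones were among them, and their RNA could fall with DNA replication, so the median over 12 genes is a weak test. Small RNA genes without the minimum had medians of -0.05 (17 snoRNA), 0.14 (14 misc_RNA), -0.57 (2 snRNA) and -0.52 (1 scaRNA). The summed CPM of nuclear mitochondrial pseudogenes changed by -530.5 while the mRNAs that fell lost 15018 CPM, so reads did not move there; a change in mitochondrial RNA processing or stability with exposure is a candidate explanation that was not tested, nor was strand-blind counting.

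Long intergenic and antisense genes leaned lower, with 157 of 2006 higher, 418 lower and a median log2 fold change of -0.22. Of the 2006, 1105 were antisense genes, whose reads cannot be told apart from those of overlapping genes with the strand setting not given. Protein-coding genes matched on abundance had a median of -0.17 (95% bootstrap interval -0.21 to -0.13), so low abundance may account for most of the shift without regard to coding. Less genomic or unspliced background in exposed libraries remained open: summed CPM of protein-coding genes below the count filter changed by -0.14 on the log2 scale, with pairs of libraries from -0.30 to -0.01, against -0.21 for the non-coding genes. Whether exposure lowers scarce transcripts was not tested apart from these.

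A hypothesis tied the lower MYC, a regulator of ribosome production, to ribosome biogenesis genes. Of 24 such genes 13 fell and 1 rose, with NOP58 at -1.19 ± 0.10 and NOP56 at -0.78 (camera adjusted p = 7.0e-04; adjusted p = 0.34 with an estimated correlation). The loss of the call with an estimated correlation leaves open whether these genes fell beyond others. A different clock phase at harvest was a candidate explanation for the clock genes, since NR1D1 and NR1D2 repress ARNTL and others. That repressed arm had a median of 0.29 (95% bootstrap interval -0.46 to 1.30) over 6 genes, most of whose values had been seen, with ARNTL at -0.82 and NFIL3 at 1.04 among them. Members moved both ways, so the test decides nothing, and the time of day at harvest is not given in the sources used here.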
